A study of Mus musculus with 2 samples.

How the data were processed

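ATAC-seq was carried out on whole lung from mouse embryos at 15.5 days, in 2 replicates of 1 group. Per the labels, each replicate was a separate pool of embryos of the strain B6NCrl, both sexes together, with 78 embryos in replicate 1 and 62 in replicate 2, and 1 technical replicate of each. The library fragments were made by transposase tagmentation, per the labels.

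The authors deposited 12 peak lists on the mouse assembly mm10, per the file headers. For each replicate there was a list before thresholding (ranked), a list filtered on the irreproducible discovery rate (IDR) and a pseudoreplicated list, all derived from the alignments of that replicate. For the series there were 2 ranked lists, an IDR thresholded list, a conservative IDR thresholded list, a replicated list and a pseudoreplicated list, all derived from the alignments of both replicates. The aligner, the peak caller, their versions and settings, any shift of the reads for the transposase, and the filters on reads are not given in the sources used here. The score of each peak is the authors' scaled score, with a cap of 1000, and the lowest score in the thresholded lists was 540, which corresponds to an IDR of 0.05 on the usual scaling of that score. The signal value, as deposited by the authors, is a ratio that was taken, from the file format and its values, to be the fold enrichment of the peak over its local background, since the sources used here do not name the measure. It was used only to describe, rank or filter peaks within a list. The deposited p-value and q-value columns are on the −log10 scale, with a lowest −log10 p of 2.00, and the −log10 of the IDR was given in the ranked lists. In each of the 2 ranked series lists, 8 further unnamed columns of values per input were not used. The files hold no read counts, so the depth of the libraries is unknown and no precision can be derived from it.

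Peaks of a list that overlapped were merged into regions, with the strongest summit of each kept. Rows on unplaced scaffolds were left out, since the annotation used here covers the main chromosomes. Chromosome names and lengths were checked against the reference sequence GRCm38.p6, and every peak on the main chromosomes lay inside it. The annotation was GENCODE M21, with 21938 protein-coding genes and 54361 transcription start sites. A region within 1 kb of the start of a protein-coding transcript was a promoter region, and every other region was distal and classed as exon, intron or intergenic by its summit. Distal regions were assigned to the nearest protein-coding start within 100 kb. A promoter was accessible when a region lay within 1 kb of any start of the gene. The conservative list was the main one, chosen in advance as the calls that both replicates support. It is not limited to regions in the lists of both replicates, since it holds 18559 regions and replicate 1 has 11119.

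Replicates were compared by the share of regions that overlapped a region of the other replicate by at least 1 bp, with exact Clopper-Pearson 95% confidence intervals, which cover counting error only. The share given by chance came from 100 shuffles of the regions within chromosomes, outside assembly gaps. Promoter and distal regions were compared with Fisher's exact test (two-sided). With 1 group of 2 replicates no p-value between samples can be given, so the units of all tests are regions or genes, which are not independent, and the p-values describe these libraries only.

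Gene lists (21 lists, 339 genes) and families (16, by symbol pattern) were tested with 10000 random lists of the same size. For promoters the random genes were matched on deciles of GC content within 500 bp of the start, and for distal regions on deciles of the length of the territory nearest to the gene. The p-values are two-sided and the smallest they can give is 0.0002. They were adjusted by the Benjamini-Hochberg method over the lists or the families. The 9 lung cell type lists (distal lung epithelium, surfactant and alveolar type 2, alveolar type 1, proximal airway epithelium, neuroendocrine and neural, mesenchyme, smooth muscle and pericyte, endothelium, mesothelium) were compared with the 8 lists of other tissues by permuting the class of the genes within the same deciles, with a smallest p-value of 0.0001. Immune, erythroid, cell cycle and housekeeping lists stayed out of that comparison.

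For 30 consensus recognition sequences, the share of regions with a match on either strand within 100 bp of the summit was compared with flanks of the same size centred 1 kb away. The fold used both flanks, and the exact McNemar test used 1 flank picked with a fixed seed, with Benjamini-Hochberg adjustment over the sequences. Promoter and distal summits were compared with Fisher's exact test. The share of the distal regions near a list's genes that the other replicate also called was compared with 10000 draws of regions of the same rank decile, for lists with 5 or more regions. Matches to the mitochondrial genome and to other places in the genome were found with blastn 2.17.0. The computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and the figures matplotlib 3.10.9.

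Sample groups, tests, gene lists, families, recognition sequences and the alternatives were chosen before the data were examined. So was the rule for the genes named in the text. It takes 13 genes in every case (Nkx2-1, Sox9, Sftpc, Foxj1, Scgb1a1, Foxf1, Tbx4, Tbx5, Acta2, Cdh5, Wt1, Ptprc and Gata1), and up to 2 members of each list with the most distal regions. It also takes up to 4 members without an accessible promoter (or with one, where fewer have one), the 20 genes with the most distal regions, the 10 regions with the highest signal value, and the Hox genes as cluster summaries. The text does not name every gene that the rule allows. Vmn1r4, Olfr71 and other single members named beside a count of 1 fall under the same rule. The members Hoxb4, Hoxb5, Hoxc4 and Hoxc13, and the split of the Hox genes by paralog number, were picked after the values were seen.

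The list tests were tested on simulated data made from the 21938 genes, with an unadjusted p below 0.05 as the call. Of 10 promoter lists of 20 genes with accessibility set to 10%, all 10 were called, of 10 set to 30%, 6 were called, and of 200 unchanged lists, 5. For lists of 10 genes these counts were 14 of 20, 4 of 20 and 2 of 200. Of 10 lists of 20 genes with 3 times the distal regions, 8 were called, with 2 times, 3 of 10, and unchanged, 7 of 200. For lists of 10 genes they were 8 of 20, 5 of 20 and 3 of 200. Small lists with moderate changes are therefore often missed. All 30 recognition sequences planted in random sequence of even base content were recovered against windows of the same content. That checks the search itself and not calls that arise from base composition.

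The alternatives were the other lists of the series, the regions with a signal value above the median, each replicate's own list in place of the list from both, promoter distances of 500 bp and 2 kb, the 5' end of the gene record only, a reciprocal overlap of at least 50%, distal regions within 50 kb, random genes without matching, windows of 50 bp and flanks 2 kb away.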

Results

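Open chromatin was profiled by ATAC-seq, in which a transposase inserts sequencing adapters into accessible DNA, in whole lungs of mouse embryos at 15.5 days of gestation. The embryos were of the strain B6NCrl and of both sexes. The series held 1 group with 2 replicates, each a separate pool of embryos. Replicate 1 came from 78 embryos and replicate 2 from 62. The list used for most counts, the authors' conservative list filtered on the irreproducible discovery rate (IDR), held 46697 summits in 18559 separate accessible regions, with a median length of 952 bp and a total of 17.9 Mb. The files give no read counts, so the depth of each library is unknown. With a single group, no comparison between conditions was possible. The comparisons made are between replicates, between gene groups and between classes of region, and regions or genes are their units.

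Nearly every region called in replicate 1 was also called in replicate 2, whereas fewer than 1 in 2 regions of replicate 2 were called in replicate 1. Replicate 1 had 11119 regions covering 9.08 Mb and replicate 2 had 23785 regions covering 20.7 Mb. Of the replicate 1 regions, 97.6% (95% confidence interval 97.3 to 97.9) overlapped a replicate 2 region, against 1.62% after shuffling. Of the replicate 2 regions, 44.9% (44.3 to 45.5) overlapped a replicate 1 region, against 0.774% after shuffling. The overlap followed the authors' signal value, taken here as the enrichment of a peak over its local background. Among the 10% of replicate 2 regions with the highest signal values, 95.8% (94.9 to 96.6) were also called in replicate 1, and among the 10% with the lowest, 10.9% (9.70 to 12.3).

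**Figure D1:**
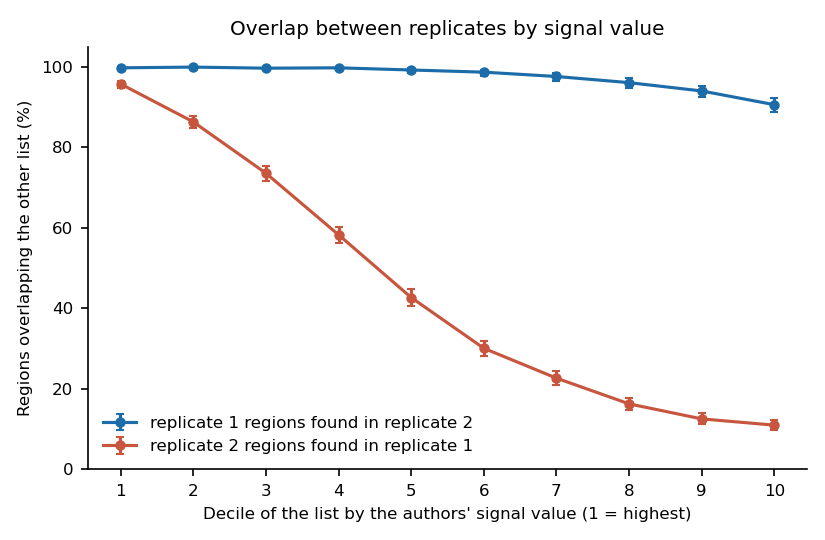
Share of the regions of each replicate that overlapped a region of the other replicate (vertical axis, percent), by decile of the list ranked on the authors' signal value (horizontal axis, 1 = highest). Points are shares and bars are exact 95% binomial confidence intervals. The share of replicate 2 regions fell from 95.8% to 10.9%, while that of replicate 1 regions stayed at 90.6% or above.

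Promoter regions, those within 1 kb of the start of a protein-coding transcript, were found in both replicates more often than distal regions. In replicate 2, 67.2% of 11933 promoter regions and 22.5% of 11852 distal regions were also called in replicate 1. The odds ratio was 7.08, and the p-value of Fisher's exact test (two-sided) was below what the computation can represent. In replicate 1, 99.2% of 8211 promoter regions and 93.0% of 2908 distal regions were also called in replicate 2 (odds ratio 9.81, Fisher's exact test, two-sided, p = 4.81e-68). Of the 13104 regions called in replicate 2 alone, 29.9% were at promoters, compared with 75.1% of the regions that both replicates shared. Neighbouring regions are not independent, so these p-values describe regions within these libraries and not embryos. The comparison was not matched on signal value. Promoter regions made up 91.7% of the decile of replicate 2 with the highest signal values and 33.2% of that with the lowest. A difference by location apart from signal value was therefore not tested.

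In the conservative list, 10833 of the 18559 regions were at promoters, which is 58.4% (57.7 to 59.1) and 15.2 times the 3.85% given by shuffled regions. Introns held 3220 regions, 17.4% (16.8 to 17.9) against 36.4% after shuffling. Intergenic DNA held 4229 regions, 22.8% (22.2 to 23.4) against 57.3%. Exons away from promoters held 277 regions, 1.49% against 2.45%. All 4 shares lay outside the range of 100 shuffles. The promoter share depended on the list, at 73.8% in replicate 1, 50.2% in replicate 2, 27.5% among the 57728 regions of the authors' replicated list and 24.5% among the 69175 of their pseudoreplicated list.

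The 10 regions with the highest signal values were all intergenic. The strongest lay on chromosome X at 143482935-143483180, with a signal value of 54.5, and its nearest transcription start was that of Pak3, a protein kinase gene, 35.5 kb away. The next were chr2:69355469-69355735 (signal value 48.3), 13 kb from Abcb11, the bile salt export pump gene, and chr2:3964425-3964690 (41.6), 53.2 kb from Frmd4a. The region chr5:60042693-60043138 (36.6) lay 1766 kb from the start of G6pd2, chr12:97061368-97061856 (28.7) lay 1182 kb from that of Galc, and chr4:80002696-80003057 (28.7) lay 831 kb from that of Tyrp1. The remaining 4 had signal values of 35.8 near Gm5426, 26.4 near Hic2, 26.3 near Myl12b and 26.2 near Gm13283. Of the 100 distal regions with the highest signal values, 13 had 2 or more further copies in the reference genome and 7 matched the mitochondrial genome, against 3 and 0 of 100 other distal regions.

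Genes of the distal epithelium and the mesenchyme mostly had accessible promoters, while the other lists of this paragraph had them for 50% of their genes or fewer. Among 20 genes of the distal lung epithelium, the progenitor layer at the growing tips of the airways, 15 had one, including Sox9, a transcription factor of the tip cells, whose region lay at chr11:112781675-112783107 with a signal value of 7.02. Among 30 genes of the lung mesenchyme, 22 had one, including Foxf1 (chr8:121083054-121084677, 7.37), a mediator of the response to hedgehog signals, and Tbx4 (chr11:85885774-85886670, 5.63), a T-box factor of the lung mesenchyme. The surfactant and alveolar type 2 list had 6 of 14, including Abca3, which exports surfactant lipid, and Lpcat1, which makes it, and the alveolar type 1 list had 7 of 14, including Hopx. In endothelium 9 of 20 promoters were accessible, including Erg and Cldn5, and in smooth muscle and pericytes 7 of 15, including Acta2 (chr19:34255166-34255721, 7.64), the smooth muscle actin gene, Myh11 and Des. Proximal airway genes had 6 of 16, including Foxj1 (chr11:116335100-116335989, 6.27), the regulator of motile cilia, and Hes1. In the replicates' own lists, the Foxf1 promoter was called in both, and those of Sox9, Tbx4, Acta2 and Foxj1 in replicate 2 only.

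None of these 7 lists passed the test against random gene lists of the same size matched on promoter GC content (permutation test, two-sided, Benjamini-Hochberg adjusted over 21 lists). The distal lung epithelium had 15 accessible promoters where 12.7 were expected (95% range 9 to 16, adjusted permutation p = 0.470), and the mesenchyme 22 where 18.5 were expected (14 to 23, adjusted p = 0.225). The alveolar type 2 list matched its expectation of 6.01 (adjusted permutation p = 1), and the alveolar type 1 list had 7 where 9.0 were expected (adjusted p = 0.470). Endothelium had 9 where 10.9 were expected (adjusted permutation p = 0.538), smooth muscle 7 where 8.53 were expected (adjusted p = 0.584) and proximal airway 6 where 9.91 were expected (adjusted p = 0.0615). Mesenchyme promoters passed as higher in the IDR thresholded list (27 of 30, adjusted permutation p = 0.0021), the pseudoreplicated list (30 of 30, 0.00105), replicate 2 alone (26 of 30, 0.00588) and without matching (22 of 30, 0.042). In the longer replicated list all 30 mesenchyme promoters were accessible (adjusted permutation p = 0.0021) and all 15 smooth muscle promoters (adjusted p = 0.0283), while proximal airway promoters were lower than random (8 of 16, adjusted p = 0.0185). Proximal airway promoters were also lower in replicate 2 alone (6 of 16, adjusted permutation p = 0.0246). In the pseudoreplicated list the alveolar type 2 and smooth muscle promoters passed as higher, with the values given below. With only the regions with signal values above the median, alveolar type 1 (2 of 14, adjusted permutation p = 0.037), endothelial (2 of 20, 0.0164), smooth muscle (0 of 15, 0.0063), distal epithelial (3 of 20, 0.0164) and mesenchymal promoters (6 of 30, 0.0164) were all lower. Smooth muscle promoters were accessible in 0 of 15 cases in replicate 1 alone, which was lower than in random lists (adjusted permutation p = 0.0042), and in 11 of 15 in replicate 2 alone.

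Several well-known lung genes had no accessible promoter at this threshold. Nkx2-1, the transcription factor that specifies the lung epithelium, had none in the conservative list and had 1 in the replicated list, and so did Bmp4 and Elf5. Fgf10, the mesenchymal growth factor that drives branching, and Tbx5, Lef1, Osr1 and Prrx1 were likewise called only in longer lists. Sftpc, which encodes surfactant protein C, and Scgb1a1, the club cell secretoglobin, had no accessible promoter in the conservative or the replicated list. Each of Nkx2-1, Sftpc and Scgb1a1 had 1 distal region, at chr12:56525365-56525786, chr14:70526632-70527381 and chr19:9081818-9082997. Cdh5, the cadherin of endothelial junctions, had 2 distal regions and no promoter call in the conservative list, and a promoter call in the replicated list. A missing call means that the promoter did not pass the threshold of the list, not that it was closed.

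Promoters of the mesothelial, neuroendocrine and neural, and immune lists, and of other tissues, were accessible less often than those of matched random genes. Mesothelial genes had 1 accessible promoter of 10, that of Krt19, where 5.82 were expected (adjusted permutation p = 0.0028), and Wt1, the mesothelial transcription factor, had none. Neuroendocrine and neural genes had 3 of 14 (Elavl4, Ret and Snap25) where 7.42 were expected (adjusted permutation p = 0.0192). Immune genes had 1 of 15, that of Ikzf1, where 6.41 were expected (adjusted permutation p = 0.0095), and Ptprc, which encodes the common leukocyte antigen, had neither a promoter nor a distal region. Erythroid genes had 3 of 14 (Epor, Klf1 and Nfe2) where 4.78 were expected, which did not pass the test (adjusted permutation p = 0.526), and Gata1, the erythroid transcription factor, had no call. Among genes of other organs, liver had 0 of 16 (expected 5.46, adjusted permutation p = 0.0031), heart muscle 2 of 15 (9.09, 0.0021), skeletal muscle 1 of 15 (8.04, 0.0028), forebrain 3 of 17 (10.1, 0.0028), intestine and pancreas 1 of 16 (7.94, 0.0021), kidney 2 of 15 (8.88, 0.0028), germ cells 2 of 15 (7.22, 0.0075) and eye and skin 1 of 16 (5.27, 0.0258).

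Cell cycle genes and housekeeping genes had accessible promoters throughout. All 16 cell cycle genes, including Mki67, the proliferation marker, and Aurkb, a mitotic kinase, had one where 10.5 were expected (adjusted permutation p = 0.0031), and all 16 housekeeping genes, including Actb and Ywhaz, where 11 were expected (adjusted p = 0.0095). In total 13 of the 21 lists passed the test, 2 with more accessible promoters than random lists and 11 with fewer. In the list of replicate 1 alone, the cell cycle (12 of 16, adjusted permutation p = 0.105), housekeeping (13 of 16, 0.0714), immune (1 of 15, 0.0934), germ cell (2 of 15, 0.105) and eye and skin (1 of 16, 0.176) lists no longer passed, and in that of replicate 2 alone the eye and skin list did not (2 of 16, 0.0594). In the replicated list the mesothelial (7 of 10, adjusted permutation p = 1), neuroendocrine (7 of 14, 0.218), cell cycle (16 of 16, 0.104) and housekeeping (16 of 16, 0.212) lists did not pass. In the pseudoreplicated list these 4 and also the forebrain (12 of 17, adjusted permutation p = 0.922) and germ cell (6 of 15, 0.0619) lists did not pass, and without matching the neuroendocrine list did not (3 of 14, 0.0605). With signal values above the median the erythroid list passed as lower (0 of 14, adjusted permutation p = 0.0391), and the neuroendocrine (2 of 14, 0.0971), germ cell (2 of 15, 0.122) and eye and skin (1 of 16, 0.152) lists did not pass. With the 5' end of the gene record only, the eye and skin list did not (1 of 16, adjusted permutation p = 0.0727).

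**Figure D2:**
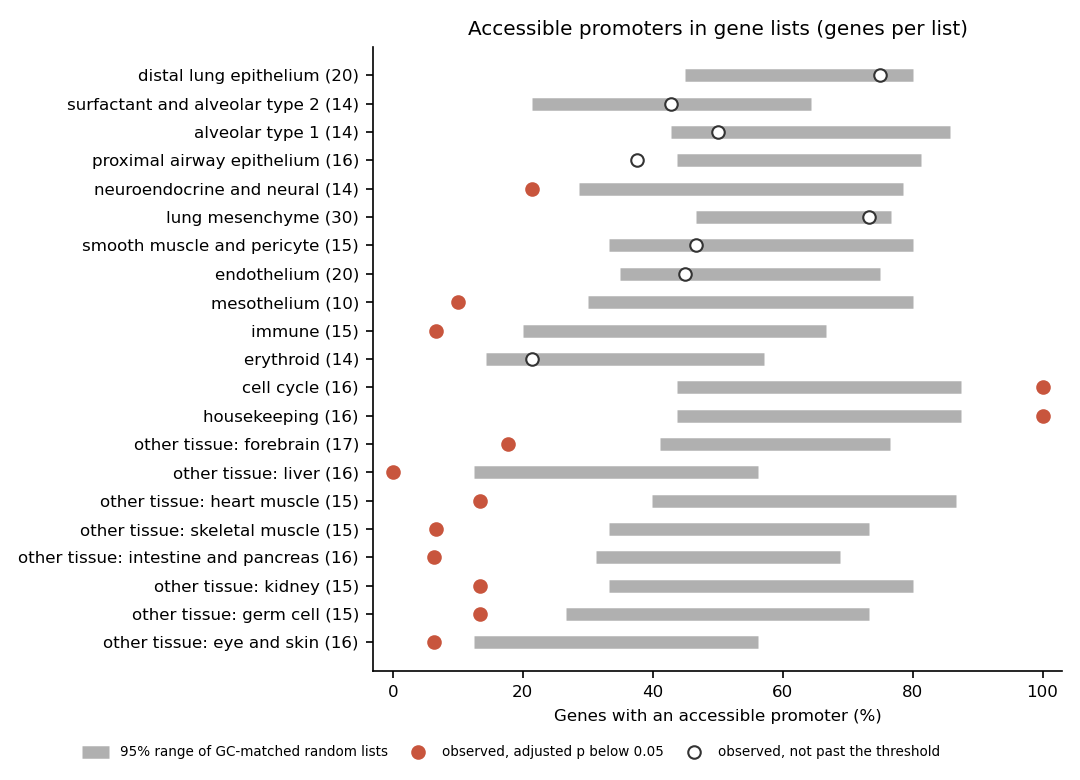
Percent of the genes of each list with an accessible promoter in the conservative list (horizontal axis), with the number of genes of each list in parentheses. Grey bars are the 95% range of random gene lists matched on promoter GC content, and filled points are lists with an adjusted p below 0.05. The cell cycle and housekeeping lists sit at 100% and the liver list at 0%.

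Taking the lists as classes, genes of the lung lists had accessible promoters more often than genes of the other-tissue lists. Of 153 genes in the 9 lung lists, 76 had an accessible promoter (49.7%), compared with 12 of 125 genes (9.6%) in the 8 lists of other tissues. The difference was 40.1 percentage points, where 5.88 were expected from GC content alone (permutation test within deciles of GC content, two-sided, p = 0.0001, the smallest it can give). It was 21.7 points in the list of replicate 1 alone and 46.3 in that of replicate 2 alone. The promoters were matched on GC content only. Whether the classes differ in the kind of gene they hold, such as breadth of expression, was not tested. Of all 21938 protein-coding genes, 51.65% had an accessible promoter, so the share of the lung genes was not above that of all genes. None of the 9 lung lists passed the GC-matched test as higher, and each of the 8 lists of other tissues passed as lower. The mesothelial list (1 of 10) and the neuroendocrine and neural list (3 of 14), which count among the lung lists, also passed as lower. Lung genes also had more distal regions than genes of other tissues, 0.791 per gene against 0.264 (permutation test within deciles of the surrounding territory, two-sided, p = 0.0025). The difference was 0.527, where 0.201 were expected from territory length alone. The distal difference of 0.527 regions per gene was 0.134 (permutation p = 0.149) when only the regions with signal values above the median were kept, and 0.186 (p = 0.0541) when regions within 50 kb of each gene were counted. It was 0.263 in replicate 1 alone and 0.738 in replicate 2 alone. Differences expected from territory length under these alternatives are not given here.

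Genes of the distal epithelium and the mesenchyme had the most distal regions per gene among the cell type lists, although neither list passed the adjusted test. The distal epithelial genes had 30 distal regions, 1.5 per gene where 0.577 were expected (permutation test, two-sided, p = 0.0048, adjusted p = 0.101). Fgfr2, the receptor for Fgf10, and Shh, the hedgehog ligand made by the epithelium, had 4 each. Shh also had 4 in each replicate, without an accessible promoter, and the 4 of the conservative list included 1 at chr5:28500841-28501830, 34.1 kb from its start. The mesenchymal genes had 34, or 1.13 per gene where 0.563 were expected (permutation p = 0.0192, adjusted p = 0.150), with 6 near Col1a1, a fibrillar collagen gene, and 3 near Axin2, a target of Wnt signalling. Endothelial genes had 14, or 0.70 per gene where 0.452 were expected (adjusted permutation p = 0.664), with 4 near Ets1 and 3 near Fli1, which both encode ETS transcription factors of endothelium. In all, 0 of the 21 lists passed the adjusted test and 3 had an unadjusted p below 0.05, the third being the germ cell list (11 regions, 0.733 per gene, expected 0.235, adjusted permutation p = 0.150), of which 7 lay near Tex14.

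The distal epithelial list passed the adjusted test in the list of replicate 1 alone (adjusted permutation p = 0.0252), which made 1 list. In the replicated list 4 lists passed, namely distal epithelium (6.5 per gene, adjusted permutation p = 0.021), mesenchyme (5.47, 0.0238), endothelium (4.90, 0.0283) and alveolar type 1 (4.21, 0.0238). In the pseudoreplicated list they were distal epithelium, mesenchyme, endothelium and smooth muscle. Distal epithelium and mesenchyme passed in the IDR thresholded list (adjusted permutation p = 0.0357 for each) and without matching (0.0021 for each), and mesenchyme alone with a 50 kb window (0.0042).

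The gene with the most distal regions was Bcas3, on chromosome 11 at 85353167-85826058, with 13, of which the strongest was chr11:85712932-85714094 (signal value 12). Replicate 1 had 9 and replicate 2 had 16. The regions lay in its introns, and downstream of the gene lie Tbx2 and Tbx4, a pair of T-box genes expressed in lung mesenchyme. The stretch from 85303167 to 85926058 held 23 regions in the conservative list, 14 in replicate 1 and 28 in replicate 2. Gse1 followed with 11, and Maml3, a coactivator of Notch signalling, Tead1, a transcription factor of the Hippo pathway, Tenm4 and Tns1 had 9 each. Cstad, Ptpn1, Sfi1 and Sik1 had 8 each, those of Sfi1 lying beside peaks left out of the authors' list, and 1700001O22Rik, 2010111I01Rik, Adamts17, Irf2bpl, Lclat1, Nav2, Ncor2, Tex14, Tex44 and Trio had 7 each. Replicate 1 alone had 0 distal regions near Tead1 and 0 near Tenm4, and replicate 2 alone had 6 and 12. The counts of this ranking were not adjusted for the length of the territory nearest to each gene. That length was 392338 bp for Bcas3, and among the ranked genes it ranged from 50249 bp for Tex44 to 627210 bp for Tenm4.

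**Figure D3:**
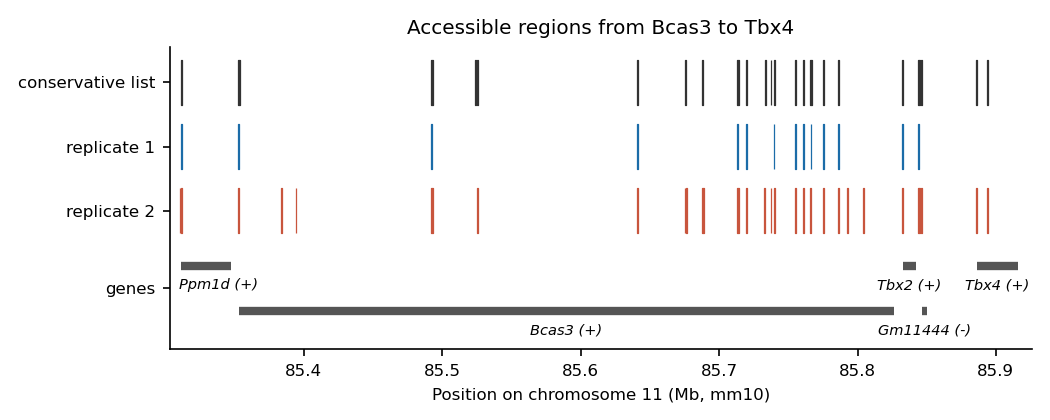
Accessible regions on chromosome 11 between 85303167 and 85926058 (horizontal axis, Mb, mm10) in the conservative list and in each replicate, drawn to scale above the protein-coding genes with their strands. The conservative list has 23 regions, replicate 1 has 14 and replicate 2 has 28, most of them within Bcas3.

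Several gene families, fixed by symbol, also differed from random genes. Ribosomal protein genes had 70 accessible promoters of 76 where 46.9 were expected (permutation test, two-sided, p = 0.0002, the smallest it can give, adjusted p = 0.00046) and were the 1 family that was higher. Of 19 Wnt genes 4 had an accessible promoter (Wnt2, Wnt2b, Wnt4 and Wnt9a) where 14.6 were expected, and of 39 Hox genes 6 where 24.2 were expected (adjusted permutation p = 0.00046 for each). Fgf genes had 7 of 22 where 13.4 were expected (adjusted permutation p = 0.0064), Bmp genes 3 of 11 where 6.59 were expected (0.0406), Tbx genes 4 of 13 where 8.03 were expected (0.0422) and Fox genes 25 of 44 where 31.6 were expected (0.0406). Olfactory receptor genes had 1 of 1093, that of Olfr71, vomeronasal receptor genes 1 of 327, that of Vmn1r4, keratin-associated protein genes 0 of 57 and beta-defensin genes 0 of 42 (adjusted permutation p = 0.00046 for each). The Klf (15 of 17), Sox (11 of 19), Irx (4 of 6), ETS-factor (17 of 26) and collagen (22 of 44) families did not pass, so 11 of the 16 families did. Sox promoters passed as lower in replicate 1 alone (5 of 19, adjusted permutation p = 0.0064) and in replicate 2 alone (10 of 19, 0.0192), and collagen promoters in replicate 1 alone (11 of 44, 0.0139). Both also passed as lower with signal values above the median (2 of 19 and 7 of 44, adjusted permutation p = 0.0016 for each).

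Several of the lower families did not pass in longer lists. In the replicated list 14 of 19 Wnt promoters (adjusted permutation p = 0.0932), 16 of 22 Fgf promoters (adjusted p = 1), 10 of 13 Tbx promoters (adjusted p = 1), 9 of 11 Bmp promoters (adjusted p = 0.977) and 34 of 44 Fox promoters (adjusted p = 0.217) were accessible, none past the test. The Wnt family passed as lower in the IDR thresholded list (5 of 19, adjusted permutation p = 0.00046), in the pseudoreplicated list (13 of 19, 0.0112) and in each replicate alone (3 and 6 of 19). In replicate 2 alone the Tbx (7 of 13, adjusted permutation p = 0.579), Bmp (7 of 11, adjusted p = 1) and Fgf (10 of 22, adjusted p = 0.0858) families did not pass, and in replicate 1 alone the Tbx family did not (3 of 13, adjusted p = 0.110). In the IDR thresholded list the Tbx (7 of 13, adjusted permutation p = 0.556), Fgf (12 of 22, 0.452) and Bmp (8 of 11, 0.866) families did not pass, and in the pseudoreplicated list neither did these 3 nor the Fox family (35 of 44, 0.284). These calls also depended on the matching, since without it the Tbx (adjusted permutation p = 0.304), Fgf (0.178), Bmp (0.296) and Fox (0.742) families did not pass, while the Klf family passed as higher (0.0096). With the 5' end of the gene record only, the Tbx (4 of 13, adjusted permutation p = 0.0593) and Bmp (3 of 11, 0.0509) families did not pass, and with signal values above the median the Tbx family did not (2 of 13, 0.0642). Receptor and defensin genes lie in arrays of similar copies, where reads can map to several places, so their counts are uncertain.

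Collagen and Wnt genes had more distal regions than random genes of similar territory. The 44 collagen genes, which encode the main proteins of the extracellular matrix, had 57, or 1.30 per gene where 0.494 were expected (permutation test, two-sided, adjusted p = 0.0011), with 6 near Col1a1, 5 near Col13a1 and 5 near Col14a1. The 19 Wnt genes had 19, or 1.00 per gene where 0.359 were expected (adjusted permutation p = 0.0312), with 4 each near Wnt11 and Wnt7b, a Wnt ligand of the lung epithelium. Olfactory receptor genes (0.0146 per gene where 0.123 were expected) and vomeronasal receptor genes (0.0153 where 0.275 were expected) had fewer (adjusted permutation p = 0.0011 for each). The other 12 of the 16 families did not pass, and 6 families had an unadjusted p below 0.05. The Wnt result was lost when only the regions with signal values above the median were kept (0.211 per gene, adjusted permutation p = 0.60) or when regions within 50 kb were counted (0.632 per gene, adjusted p = 0.428).

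In the Hox clusters, which encode positional identity along the body axis, accessible promoters were found in Hoxa on chromosome 6 (3 of 11: Hoxa1, Hoxa4 and Hoxa5) and in Hoxb on chromosome 11 (3 of 10: Hoxb2, Hoxb4 and Hoxb5). Hoxc on chromosome 15 and Hoxd on chromosome 2 had 0 of 9 each. Hoxa5, a regulator of lung morphogenesis, had the region with a signal value of 7.29. In the replicates' own lists, the promoters of Hoxa1, Hoxa5 and Hoxb5 were called in both, and those of Hoxa4, Hoxb2 and Hoxb4 in replicate 2 only. The Hoxc13 promoter was also called in replicate 2 only, and the IDR thresholded list of the series held those of Hoxc4 and Hoxc13. By paralog number, 6 of 15 genes numbered 1 to 5 and 0 of 24 genes numbered 6 to 13 had an accessible promoter, a split chosen after the values were seen and not tested. In the IDR thresholded list of the series these counts were 7 of 15 and 1 of 24, and in replicate 2 alone 6 of 15 and 1 of 24. The replicated list had 11 of 15 and 10 of 24, with 4 of 9 promoters in Hoxc and 5 of 9 in Hoxd.

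**Figure D4:**
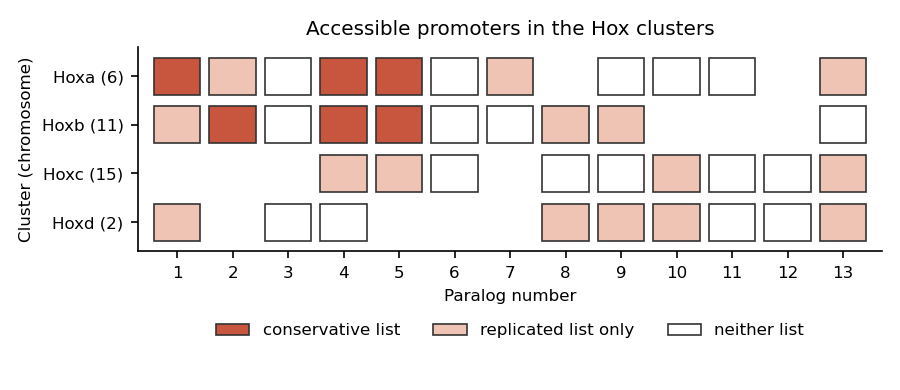
Promoters of the 39 Hox genes, with clusters on the vertical axis (chromosome in parentheses) and paralog numbers on the horizontal axis. Dark boxes are accessible in the conservative list, light boxes only in the replicated list and white boxes in neither. The 6 dark boxes lie at numbers 1 to 5 of Hoxa and Hoxb.

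Distal summits carried the recognition sequences of TEAD factors, of E-box binding factors of the MYOD type and of CTCF more often than their flanks. The TEAD sequence, bound by the effectors of the Hippo pathway, was found within 100 bp of 8.39% (7.78 to 9.03) of 7726 distal summits and in 3.24% of flanks 1 kb away (2.59-fold, adjusted exact p = 8.11e-48). The MYOD-type E-box was found at 8.01% (7.42 to 8.64) against 2.36% (3.39-fold, adjusted exact p = 6.68e-53), and CTCF, which shapes chromatin loops, at 2.19% against 0.162% (13.5-fold, adjusted p = 1.23e-36). SP/KLF sequences were found at 4.85% (6.15-fold, adjusted exact p = 1.79e-52) and NFY sequences at 4.91% (2.38-fold, adjusted p = 3.33e-22). AP-1 was found at 5.57% (1.48-fold, adjusted exact p = 6.89e-08), FOX, the sequence of forkhead factors, at 7.33% (1.37-fold, adjusted p = 8.76e-06), SRF at 0.401% (5.64-fold, adjusted p = 3.52e-05) and MEF2 at 0.595% (2.04-fold, adjusted p = 0.012). NKX2-1 was found at 3.25% against 2.72% (1.2-fold, adjusted exact p = 0.111), SOX at 6.54% (1.01-fold, adjusted p = 0.809) and GATA at 4.58% (1.03-fold, adjusted p = 0.607), none past the threshold. NKX2-1 passed in the IDR thresholded (1.26-fold, adjusted exact p = 8.36e-05), replicated (1.29-fold, 1.08e-12) and pseudoreplicated (1.29-fold, 2.61e-12) lists and with flanks 2 kb away (1.24-fold, 0.00443), but in neither replicate alone. GATA passed in the same 3 lists (up to 1.21-fold, adjusted exact p = 3.77e-13) and in replicate 2 alone (1.13-fold, 0.0499). The TBX and IRF sequences were rarer at distal summits than in flanks (0.588-fold, adjusted exact p = 0.000212, and 0.443-fold, adjusted p = 7.14e-12). The TBX result did not pass in the replicated list (0.968-fold, adjusted exact p = 0.912), in replicate 1 alone (0.5-fold, p = 0.198), with signal values above the median (0.5-fold, p = 0.390) or with flanks 2 kb away (0.672-fold, p = 0.0597).

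The SP/KLF, NFY, ETS, NRF1 and YY1 sequences were more frequent at promoter summits than at distal summits, and were enriched over flanks at both. At distal summits YY1 rested on 6 summits against 0 flanks (adjusted exact p = 0.0469), and NRF1 on 20 summits against 3 flanks. Only starts of protein-coding transcripts were used, so regions at the starts of other genes count as distal. SP/KLF sequences were found at 23.0% (22.2 to 23.8) of 10833 promoter summits, 15-fold above flanks, and NFY sequences at 16.4% (15.7 to 17.1), 9.37-fold above flanks, both with p-values below what the computation can represent. ETS sequences were found at 7.21% (25.2-fold, adjusted exact p = 1.08e-183), NRF1 at 1.64% (32.4-fold, adjusted p = 2.78e-43) and YY1 at 1.26% (45.7-fold, adjusted p = 1.2e-37). FOX (0.329-fold), GATA (0.244-fold), NKX2-1 (0.282-fold) and TEAD (0.547-fold) sequences were rarer at promoter summits than in flanks. Compared directly, TEAD was more frequent at distal than at promoter summits (8.39% against 1.74%, adjusted p = 9.3e-103, Fisher's exact test, two-sided), as were FOX (7.33% against 1.87%, adjusted p = 2.18e-74) and NKX2-1 (3.25% against 0.738%, adjusted p = 1.05e-36). In all, 18 of the 30 sequences were more frequent at distal summits and 5 at promoter summits. GC content was 66.7% at promoter summits, 46.9% in their flanks and 55% at distal summits. These comparisons were not matched on it, so the part that base composition plays in them was not tested.

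Against flanks, 18 of 30 sequences were enriched and 2 depleted at distal summits, and 10 were enriched and 14 depleted at promoter summits (exact McNemar tests, two-sided, Benjamini-Hochberg adjusted). In the list of replicate 1 alone 9 were enriched at distal summits, and AP-1 (1.35-fold, adjusted exact p = 0.058), FOX (1.16-fold, adjusted p = 0.661) and MEF2 (2.25-fold, adjusted p = 0.221) no longer passed. With signal values above the median 8 were enriched, and FOX (1.12-fold, adjusted exact p = 0.175), AP-1 (1.38-fold, 0.133), MEF2 (1.22-fold, 0.786) and SRF (7-fold, 0.140) no longer passed. MEF2 did not pass with 50 bp windows (2.19-fold, adjusted exact p = 0.134) or flanks 2 kb away (1.61-fold, 0.110) either. Summits were richer in GC than flanks, at 66.7% against 46.9% for promoters and 55% against 46.1% for distal regions. Read in mirrored order, the TEAD sequence was rarer at distal summits than in flanks (0.730-fold), and the MYOD E-box was more frequent (3-fold, 18 summits). The match is to a short consensus and does not show binding.

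**Figure D5:**
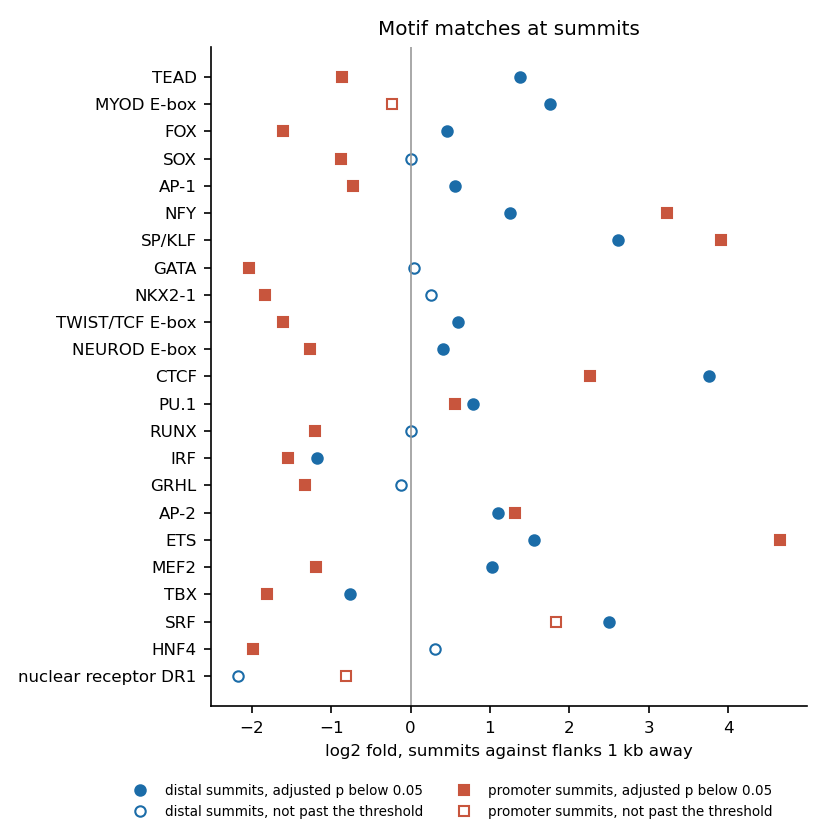
Fold of each of 23 recognition sequences at summits against flanks 1 kb away (horizontal axis, log2), for distal summits (circles) and promoter summits (squares). Filled symbols have an adjusted p below 0.05 in exact McNemar tests. TEAD and the MYOD E-box lie above 0 at distal summits, at 1.37 and 1.76, and TEAD lies at -0.87 at promoter summits.

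The regions called in replicate 2 alone were not concentrated near the genes of any cell type list past the adjusted test. Of 42 distal regions of replicate 2 near distal epithelial genes, 15 (35.7%) were also called in replicate 1, where 20.9% (95% range 9.52 to 33.3) were expected from regions of the same rank (permutation test, two-sided, p = 0.0216, adjusted p = 0.302). Near mesenchymal genes it was 13 of 49 (26.5%, expected 23.5%), near endothelial genes 5 of 19 (26.3%, expected 20.7%) and near smooth muscle genes 0 of 11 (expected 17.0%, permutation test, adjusted p = 0.928). Of the 14 lists with 5 or more distal regions, 0 passed the adjusted permutation test and 1 had an unadjusted p below 0.05. In the reverse direction 0 of 5 lists passed and 0 had an unadjusted p below 0.05, with 16 of 17 distal epithelial and 14 of 16 mesenchymal regions of replicate 1 called in replicate 2. When the pseudoreplicated list of each replicate was used instead, 2 gene lists differed in the share of replicate 2 regions called in replicate 1.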

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

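The test of copies in the reference was chosen before its result was seen. The test of mitochondrial copies was split, with new bounds, into the whole cause and a part only after its result was seen, and the alignment of the left-out region with the highest −log10 p to the mitochondrial genome was chosen after that region was seen.

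Peaks that reached the score of a thresholded list were missing from that list, and the comparisons of the report do not use them. On the main chromosomes they formed 62 regions for replicate 1, 65 for replicate 2, 78 for the IDR thresholded list of the series and 69 for the conservative list. Of the 69, the region with the highest −log10 p, 6298, was chr1:24611587-24616170, 4584 bp long, with a signal value of only 3.54, and 100% of its length aligned to the mitochondrial genome, at an identity of up to 99.96%. The other 68 regions had no such alignment. Those with the highest signal values were chr9:24541943-24542230 (47.2) and chr6:103648978-103649357 (42.9). Several of the 69 lay close together near the start of chromosome 9, near position 19416117 of chromosome 14 and near position 98662181 of chromosome 2, and 4 lay between 3161078 and 3196895 of chromosome 11, in or next to Sfi1, so the 8 distal regions counted for that gene (signal values 2.44 to 5.61) are uncertain. Peaks on unplaced scaffolds numbered 121 in the ranked list of replicate 1 and 186 in that of replicate 2.

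The distal regions with the highest signal values, of which 80 of the top 100 were intergenic against 53 of 100 other distal regions drawn at random, were weighed against technical sources of signal. Sequence present in several copies fits a part of them, since 13% (95% confidence interval 7.11 to 21.2) had 2 or more further copies in the reference, against 3% of the others (odds ratio 4.83, Fisher's exact test, two-sided, p = 0.0165). Single duplicates, more diverged copies and copies missing from the reference were not measured. For nuclear copies of mitochondrial DNA the test set in advance gave no verdict, since 7 of the 100 (2.86 to 13.9) matched the mitochondrial genome against 0 of the others, between the bounds of 20 and 5. Read after the result, an interval below 20 argues against them as the whole cause, and as the cause of a part they stay open, since it includes 5. The top 100 were not farther from genes than the others, with median distances to the nearest start of 30.8 and 31.7 kb. The design names no groups, so no biological explanation was tested.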

How the results depend on the processing

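The alternatives were all chosen before the results were seen. Of the 113 alternative values of the 18 results that answer a comparison, 81 were kept, 30 moved and 2 no longer passed. A test was kept if its direction and side of the threshold stayed, a count if it stayed within 1.5 times. A share of overlap was kept within its confidence interval. The share of a class of region was kept within the standard deviation of the shares of the 2 single replicates. That spread is wide and was built from 2 of the alternatives it judged, so it is no independent check of them. Of 833 values of 100 single lists, families, classes and sequences, 680 were kept, 66 passed a threshold that the main value did not, 60 no longer passed, 14 moved and 13 reversed.

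The number of regions, 18559 in the conservative list, was 57728 in the replicated list, 69175 in the pseudoreplicated list, 9279 with signal values above the median and 46697 with each summit counted, which follows from how these lists are made. From the list of a single replicate it ranged from 11119 to 23785. The promoter share moved to 27.5% in the replicated list, 24.5% in the pseudoreplicated list and 77.3% with signal values above the median, and ranged from 50.2% to 73.8% over single replicates. Replicate 1 regions overlapped replicate 2 in 88.1% of cases and the reverse in 41.2% with a reciprocal overlap of at least 50%, in 79.8% and 42.9% in the pseudoreplicated lists, and in 97.9% and 45.8% with signal values above the median of each list.

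The number of families whose promoters passed, 11 in the conservative list, was 6 in the replicated and 7 in the pseudoreplicated list. Lists passing for distal regions, 0 in the conservative list (3 at an unadjusted permutation p < 0.05), numbered 2 in the IDR thresholded list, 4 in the replicated, 4 in the pseudoreplicated, 1 with a 50 kb window and 2 without matching, and from 0 without replicate 1 to 1 without replicate 2, distal lung epithelium with 0.85 regions per gene (adjusted permutation p = 0.0252). Families passing for distal regions, 4 in the conservative list, numbered 7, 8 and 9 in those 3 longer lists, 9 with a 50 kb window and 9 without matching. The difference between lung and other lists in distal regions was 0.134 with signal values above the median (permutation p = 0.149) and 0.186 with a 50 kb window (permutation p = 0.0541). In the conservative list it was 0.527, where 0.201 were expected from territory length alone. Sequences enriched at distal summits, 18 in the conservative list, numbered 8 with signal values above the median, and from 9 without replicate 2 to 20 without replicate 1. In the pseudoreplicated lists 2 gene lists differed in their recovery in replicate 1, against 0 (1 at an unadjusted permutation p < 0.05). The cause of these changes was not tested.

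The direction reversed in 13 cases, 1 of them (GRHL) only by the counts of the paired test. Accessible Bmp promoters, 3 of 11 and fewer than expected, numbered 8 in the IDR thresholded, 9 in the replicated and 9 in the pseudoreplicated list, more than expected but not past the test, and from 1 to 7 over single replicates, 7 without replicate 1 being more than expected. Fgf promoters numbered 17 in the pseudoreplicated list. Smooth muscle promoters numbered 15 in the replicated and 15 in the pseudoreplicated list (adjusted permutation p = 0.0283 and 0.0428, higher than expected), and alveolar type 2 promoters 12 in the pseudoreplicated list (0.0361, higher). With signal values above the median, distal epithelial promoters fell to 3 and mesenchymal promoters to 6 (adjusted permutation p = 0.0164 for each, lower), and the GRHL sequence was 0.357 times as frequent at distal summits as in flanks. Its fold in the conservative list was already below 1, at 0.923, where 66 summits and 57 single flanks alone had it. Without matching, the 25 Fox promoters were more than expected. With a 50 kb window, ribosomal protein genes had 0.763 distal regions per gene, more than expected. The cause was not tested.

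Depth is unknown, so it cannot be said how many regions missing from replicate 1 a deeper library would hold. Promoter calls of lists with few genes are limited by their size, since lists of 10 genes set to 30% accessibility were called in 4 of 20 simulations.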

Other observations

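The test of the TEAD and MYOD E-box sequences was read for each sequence apart only after its result was seen, and the other tests were chosen before theirs.

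Several developmental genes had many distal regions and no accessible promoter in the conservative list. Shh had 4 distal regions and no promoter call, also in the replicated list. Wnt11 and Wnt7b had 4 each, Maml3 had 9, Col14a1, a fibril-associated collagen gene, had 5, and Fli1 had 3. Near Shh, Wnt11, Wnt7b and Maml3, replicate 1 had 4, 5, 5 and 7 distal regions and replicate 2 had 4, 6, 6 and 10. Near Col14a1 and Fli1, replicate 2 had 7 and 2 and replicate 1 had 0. In the replicated list, Wnt11, Wnt7b, Maml3, Col14a1 and Fli1 each had an accessible promoter, and Wnt11 also had one in replicate 2. No test compared these genes with others.

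The germ cell gene Tex14, on chromosome 11 at 87405065-87555823, had 7 distal regions, all in its introns, and 6 in each replicate. The strongest were chr11:87461853-87462931 (signal value 14.8), chr11:87470824-87471992 (13.9), chr11:87442692-87443833 (13.3) and chr11:87448202-87449270 (10.5). On average 19.9% of the bases of its distal regions were marked as repeats in the reference, against 11.6% for all distal regions. Its promoter was also accessible (signal value 9.72), while 13 of the 15 germ cell promoters were not. A region counts for every gene with a start within 1 kb, so this call need not be that of Tex14 alone. In the replicated list its count was still 7, where Bcas3 went from 13 to 27 and Gse1 from 11 to 32.

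Replicate 2 had 23785 regions and replicate 1 had 11119, and of the 13104 regions in replicate 2 alone, 67.7% (66.9 to 68.5) were in the ranked list of replicate 1 before thresholding, against 1.83% of shuffled regions. This share lies between the 80% set in advance for weaker enrichment or depth of the replicate 1 library and the 50% set against it, so that explanation stays open as the whole cause, with 81.6% at promoters and 61.7% at distal regions. A different cell makeup of the pools also stays open, since among lists with 20 or more regions the largest difference between the recovered and the matched share was 14.8 percentage points, for distal epithelial genes (35.7% against 20.9%, matched range 9.52 to 33.3%, permutation test, adjusted p = 0.302). The bounds set in advance against it, 15 points for the difference and 15 either side for the range, were both met, so the rule as set went against it. It is left open by a stricter reading that the rule did not state, since the difference met its bound by less than its spread. Of 14 lists, 0 differed after adjustment and 1 at an unadjusted permutation p < 0.05, and in the pseudoreplicated lists 2 differed. These tests cover distal regions only, and no test compared the promoters of a list between the replicates. Among smooth muscle genes, accessible promoters numbered 0 of 15 in replicate 1 and 11 of 15 in replicate 2. The design has no groups, so no biological explanation was tested.

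The TEAD and MYOD E-box sequences at distal summits were weighed against base composition, with log2 folds of 1.37 and 1.76 over flanks. The mirrored TEAD sequence, which has the same bases in reverse order, was below its flanks, at -33.1% of the log2 fold (95% interval -60.2 to -8.81, 85 summits). This argues against the content of single bases as the cause for TEAD. The mirrored sequence can hold a CG pair, unlike TEAD, and was found in 1.51% of flanks against 3.24% for TEAD, so pairs of neighbouring bases were not controlled for. For the MYOD E-box the mirrored sequence reached 89.95% of the log2 fold (28.6 to 166), from 18 summits, and unlike the E-box it contains a CG pair, so base composition cannot be told apart from a preference for the sequence. Both sequences match several factors, and no biological explanation was tested.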
